A study of Danio rerio with 6 samples.

How the data were processed

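RNA from single brains of 3 zebrafish exposed to low oxygen and 3 at ambient oxygen was measured on 6 Affymetrix Zebrafish Gene 1.0 ST arrays. Per the labels, total RNA with an integrity number above 7.0 was used, 300 ng was converted to amplified sense-strand cDNA, labelled with biotin and hybridised at 45 °C for 16 h. The authors adjusted the intensities with RMA background correction and quantile normalization, per the series' design text, and the submitters' processing notes name Affymetrix Expression Console and RMA, with versions not given in the sources used here. The deposited values are log2 values with 2 decimals, as judged from their range of 1.62 to 14.34 and their column medians of 6.28 to 6.60. The probe set level and any filter applied are not given in the sources used here. The arrays keep unequal medians and spread, so summarised values were not equalised, and a shift between arrays that depends on level can enter any difference between groups.

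Of 75212 rows, 20806 named 1 gene in the platform annotation, 855 named several and 53551 (71.2%) were unnamed here. Gene symbols were updated through the Entrez identifier, which matched 20323 rows and changed 1 symbol. A gene's value was the mean of the rows that named it alone, which gave 19260 genes. Of these, 1365 had several rows, and in 554 the rows differed in the sign of the change. Rows that named several genes or none were tested apart from the genes: of 54406 such rows limma called 0, with 2324 at an unadjusted p under 0.05, fewer than chance alone gives. No filter on dim genes was applied. Arrays give no count of molecules, so precision rests on the 3 fish per group.

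Groups came from the sample titles. Differences are hypoxia minus normoxia on the log2 scale, tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 6 arrays, no covariate) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. There were 43 gene lists (27 pathways and 16 cell types), tested with camera at a preset correlation of 0.01 and adjusted over the 43. Each list was also tested with an estimated correlation, with fry, against 10000 random lists matched in 50 bins of mean level, and by an exact two-sided permutation of its score (the mean over members of the log2 value minus the gene's mean), whose smallest p is 0.1.

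Genes were named by a rule. For each direction it took genes past the threshold with no overlap between groups, up to 12 with the largest change, filled to 12 with the smallest p among informative symbols. It added up to 4 members with the smallest p from each pathway list and from each cell type list that passed or had a median beyond 0.25 in size, and a fixed set of genes of hypoxia and of Alzheimer's disease. 2 genes of that set were not analysed here. Some genes in the accounts of single arrays were named after their values were seen, namely LOC100535170, gh1, prl, pomca, cga, smtlb, pomcb, chga, exorh, rcvrnb, fkbp5, LOC100002043 and ptgr1.1. Lists, the rule and the tests of the comparison were fixed before the data were examined, and the tests of explanations and the alternatives named as added were chosen later.

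The procedure was tested on simulated data for the comparison of hypoxia with normoxia over 19260 genes. It recovered 23% of 100 genes changed by 1 log2 unit and 82% of 100 changed by 2, and called 2 unchanged genes. The simulated noise was independent between genes, without the correlation between genes or the unequal array spread of the real data. In it 1 list was called, the one that was shifted, while other splits of the real arrays called 7 to 23 lists. The simulated performance may therefore not carry over to these arrays. Alternatives were a replicate block, each array left out in turn, other scalings, filters on dim genes, the brightest row per gene, an intensity trend, robust moderation, array weights, all rows in place of genes, other thresholds, other set tests and lists without shared genes. Array spread as a covariate, quantile normalization of all rows and leaving out hypoxia 3 and normoxia 3 together were added after the data were seen.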

Results

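Gene expression was measured in the brains of 6 adult zebrafish (Danio rerio, Tübingen strain, about 1 year old), with 1 brain per Affymetrix Zebrafish Gene 1.0 ST array. For 3 fish the water had been depleted of oxygen with nitrogen to 1.20 ± 0.6 mg/l and exposure lasted 3 h, and 3 fish were at ambient oxygen of 6.6 ± 0.45 mg/l (the kind of error is not given in the sources used here). Fish are called hypoxia 1 to 3 and normoxia 1 to 3. The deposited log2 values ran from 1.62 to 14.34, and the number of arrays limits the precision. The single comparison, hypoxia minus normoxia, asks which brain transcripts differ after 3 h of low oxygen.

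The genes with the smallest p included an unnamed locus, an egg coat gene and psat1. LOC100535170 was higher in all 3 hypoxia brains, with a log2 value of 5.79 ± 0.14 against 3.36 ± 0.29 (mean ± SD, n = 3 fish each), a difference of 2.43 (SE 0.204, limma adjusted p = 0.0146). It has no informative name and was picked out after its values were seen. It was the 1 gene of 19260 to pass the threshold. It is dim, with both group means below 6, and the 2001 genes with a mean below 6 had a median log2 difference of 0.09. zp3.2, of a family of egg coat glycoproteins, was 7.06 ± 0.04 in hypoxia and had a log2 difference of 1.55 with adjusted p = 0.0602, which does not pass. It passed without normoxia 2 (limma adjusted p = 0.0285) and after quantile normalization of gene values (0.0377) or of all rows (0.0472). It also passed with array weights, which says little, since 7550 genes did so with a weight of 39.9 on normoxia 3. With an array other than normoxia 2 left out, the adjusted p of zp3.2 was 0.195 to 0.722. psat1, which encodes an enzyme of serine synthesis, had a log2 difference of -1.55 (adjusted p = 0.248), and its values of 7.85, 8.21 and 8.10 in hypoxia all lay below the normoxia values of 9.23, 9.77 and 9.80.

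Among the other informative names with the smallest p, none passed. Those higher in hypoxia included the trace amine receptor genes taar20u (1.06) and taar10d (1.57), the immune-type receptor genes nitr1b (1.45) and nitr3a (1.34), the odorant receptor genes or64b4 (0.75) and or70c1 (0.89) and the complex I subunit gene ndufa9b (0.96), given as log2 differences. Those lower included ggact.2 (-2.31), igfbp7 (-1.19), TIMP4 (-1.10), msrb2 (-1.72), bhmt (-1.19), tlx3a (-1.35) and rbpms2b (-1.15). Their adjusted p was between 0.376 and 0.72. Several were dim, with means below 6 in both groups. Means in hypoxia and normoxia were 4.81 and 3.75 for taar20u, 4.83 and 3.39 for nitr1b, and 5.45 and 4.11 for nitr3a. They were 4.91 and 3.95 for ndufa9b and, among those lower, 3.61 and 5.93 for ggact.2. At an unadjusted p under 0.05 there were 1283 genes, 174 higher and 1109 lower, where chance alone gives 963. Leaving out 1 array moved this to 105 higher and 402 lower without hypoxia 1, fewer than chance gives, and to 1602 and 3145 without normoxia 2. With the arrays shifted to equal medians that split became 559 higher and 492 lower, because the median log2 difference of all genes moved from -0.08 to 0.06. Of all genes, 11761 had a lower mean in hypoxia and 7499 a higher one. Among genes above the median level 23.2% were higher, which is the background for counts in lists of bright genes. The 54406 rows that name several genes or none had the opposite balance, with 1620 higher and 704 lower at an unadjusted p under 0.05 and a median of 0.09. Those 2324 rows are fewer than chance alone gives. The values of hypoxia and normoxia did not overlap in 2185 genes, 11.3% of those tested, where chance gives 10%. The call of LOC100535170 was lost when any array except normoxia 2 was left out, with adjusted p from 0.0645 to 0.181, and without normoxia 2 there were 17 genes past the threshold, 2 higher and 15 lower.

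**Figure D1:**
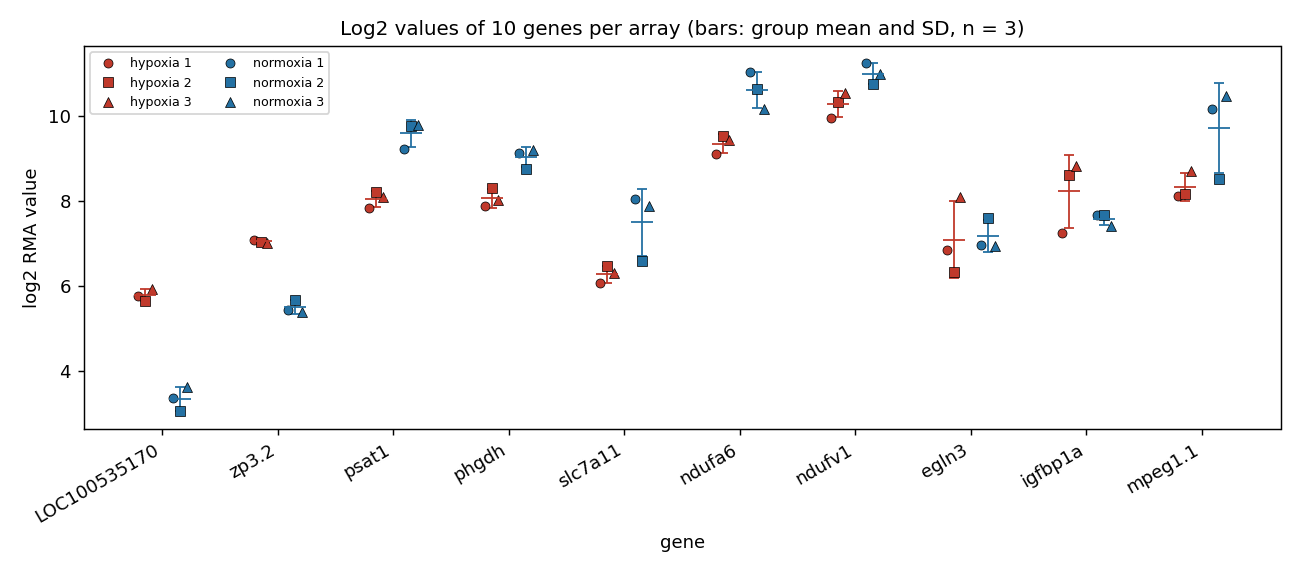
Log2 RMA values (vertical axis) of 10 genes in each of the 6 arrays, with group means and SDs as bars (n = 3). LOC100535170, zp3.2, psat1 and phgdh show no overlap between hypoxia (red) and normoxia (blue), while the egln3 and igfbp1a values of the groups overlap.

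Genes induced through hypoxia-inducible factor (HIF) were measured as a list fixed before the data were examined. Of 51 measured members of the hypoxia-inducible targets, 19 were higher and 32 lower in hypoxia, with a median log2 difference of -0.09 (-0.127 to -0.00167 with 1 array left out), and none passed over all genes or adjusted over the list alone. egln3, a prolyl hydroxylase that HIF induces, was 6.85, 6.34 and 8.10 in hypoxia and 6.97, 7.61 and 6.96 in normoxia. igfbp1a was 7.26, 8.61 and 8.84 in hypoxia against 7.68, 7.69 and 7.42. The glycolytic regulator pfkfb4b had a log2 difference of 0.62, vegfaa one of -0.25, ldha one of -0.48 and bnip3 one of -0.34, which without hypoxia 1 became -0.02, -0.10 and 0.00 and without hypoxia 3 -0.45, -0.75 and -0.59, and ndrg1a (-0.91) and the glucose transporter gene slc2a1a (-0.77) were lower. The list did not differ from other genes (camera adjusted p = 0.622, direction up, opposite in sign to the median) and the exact two-sided permutation p of its score was 0.6, where 0.1 is the smallest that 3 against 3 fish allow. Its median was 0.05 with equal array medians. In the HIF pathway core itself 12 of 14 genes were lower, with a median at percentile 37.4 among random lists of like level. Its camera adjusted p was 0.501, or 0.0251 as lower without hypoxia 3 and normoxia 3 together, an alternative added after the data were seen. There hif1al had a log2 difference of 0.69 and hif1ab one of -0.19, which was -0.09 without normoxia 1 and -0.40 without normoxia 2.

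Genes of mitochondrial respiration were lower together. All 60 measured genes of oxidative phosphorylation had lower means in hypoxia, with a median log2 difference of -0.44 (camera adjusted p = 3.5e-12, and adjusted p = 0.753 with an estimated correlation, where members correlated at 0.441). This median was -0.30 with equal array medians, -0.28 after quantile normalization of gene values and -0.20 with array spread as a covariate, an alternative added after the data were seen. Among them the complex I subunit genes ndufa6 (-1.26), ndufb2 (-0.63) and ndufv1 (-0.72) and the cytochrome oxidase subunit gene cox4i2 (-0.88) had the smallest p. ndufa9b, a complex I subunit gene outside the list and dim at 4.91 ± 0.23 in hypoxia and 3.95 ± 0.04 in normoxia (n = 3), had a log2 difference of 0.96 (adjusted p = 0.702). No member of the list passed over all genes, and 1, ndufa6, passed adjusted over the list alone (adjusted p = 0.0378). The score of the list was -0.22 ± 0.21 in hypoxia and 0.22 ± 0.23 in normoxia (mean ± SD, n = 3), with an exact permutation p of 0.1, the smallest possible. The score of hypoxia 3, -0.05, was next to that of normoxia 2, -0.04. The list passed the same preset-correlation threshold in 7 of the 9 other splits of the 6 arrays. An exact permutation p of 0.1 was not particular to oxidative phosphorylation: 5 of the 43 lists had it, where chance gives 10%. The others were oxidative stress and Nrf2 targets, angiogenesis and vascular signalling, endothelium, and pericyte, smooth muscle and fibroblast.

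Other lists of central metabolism were lower to a smaller degree. In the TCA cycle 25 of 27 genes were lower, with a median of -0.28 (adjusted p = 0.00238, and adjusted p = 0.753 with an estimated correlation), led by suclg1 (-0.56), idh3b (-0.59) and sucla2 (-0.63). In glycolysis 27 of 32 were lower, with a median of -0.20 (adjusted p = 0.0367, and adjusted p = 0.753 with an estimated correlation), led by eno1b (-1.05), pgk1 (-0.59) and aldoca (-0.77). Without hypoxia 1, sucla2 was -0.39 and aldoca -0.49. No member of these lists passed, over all genes or over the list alone. The call of glycolysis was also lost without hypoxia 1 (0.5) or normoxia 2 (0.222), and its mean change minus that of other genes ran from -0.22 to -0.04 with 1 array left out. After quantile normalization of gene values the adjusted p was 0.0627 for the TCA cycle and 0.272 for glycolysis, and with array spread as a covariate, added after the data were seen, 0.602 and 0.32. With equal array medians the median of the TCA cycle was -0.14 and that of glycolysis -0.06, and after quantile normalization of gene values they were -0.07 and -0.03. Both medians lay inside the middle 95% of 10000 random lists of like level, at percentiles 3.97 and 23.1.

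Lists of protein quality control and stress response were lower as well. In the unfolded protein and integrated stress response 40 of 46 genes were lower, with a median of -0.35 (adjusted p = 0.00011, and adjusted p = 0.753 with an estimated correlation). The exact permutation p of its score was 0.2. Its members with the smallest p were not chaperones but genes of amino acid supply, namely psat1, phgdh (-0.96) and shmt2 (-0.71) of serine and glycine synthesis and the cystine transporter gene slc7a11 (-1.22). psat1 and phgdh passed adjusted over the list alone, and none passed over all genes. The proteasome list was lower in 31 of 33 genes, with a median of -0.35 (adjusted p = 0.000116, and adjusted p = 0.753 with an estimated correlation). Its mean change minus that of other genes went from -0.244 to -0.142 without hypoxia 1, and that of the unfolded protein response from -0.276 to -0.185 without normoxia 3. Heat shock and chaperones (26 of 37 lower, adjusted p = 0.0367), oxidative stress and Nrf2 targets (28 of 39, adjusted p = 0.0212), angiogenesis and vascular signalling (32 of 42, adjusted p = 0.0292) and mitochondrial dynamics, mitophagy and autophagy (31 of 39, adjusted p = 0.0439) had medians from -0.26 to -0.18. For these 4 lists adjusted p = 0.753 with an estimated correlation, or 0.772 for mitochondrial dynamics. Examples were hspb6 (-0.86), pgd (-1.10), cxcl12b (-1.31) and ctsd (-0.93), none of which passed. Much of the counts of lower genes in these 4 lists is background, since only 38.9% of all genes were higher in hypoxia. Of genes above the median level 23.2% were higher, a share that need not hold for dimmer members. The mean levels of the 4 lists ran from 7.58 for angiogenesis to 8.78 for mitochondrial dynamics. Medians of heat shock (percentile 0.65), oxidative stress (1.25) and angiogenesis (0.77) still lay below the middle 95% of random lists of like level. Leaving out 1 array ended the call of heat shock and chaperones (adjusted p = 0.322 without hypoxia 1, 0.164 without normoxia 1, 0.101 without normoxia 3), of oxidative stress and Nrf2 targets (0.0718 without normoxia 2), of angiogenesis and vascular signalling (0.0506 without hypoxia 3, 0.119 without normoxia 2) and of mitochondrial dynamics, mitophagy and autophagy (0.321 without hypoxia 1, 0.419 without normoxia 1, 0.0642 without normoxia 3). With array spread as a covariate, an alternative added after the data were seen, none of the 6 passed: adjusted p was 0.291 for the unfolded protein and integrated stress response, 0.0847 for the proteasome, 0.293 for oxidative stress and 0.32 for angiogenesis, and heat shock (0.883) and mitochondrial dynamics (0.602) changed direction. After quantile normalization of gene values the unfolded protein response (0.0175) and the proteasome (0.0115) passed, with medians of -0.20 and -0.15, and the other 4 did not, with medians of -0.08 for heat shock, oxidative stress and angiogenesis and of -0.000556 for mitochondrial dynamics. The median of mitochondrial dynamics was at percentile 32.1 among random lists of like level.

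Immediate early genes, which neurons switch on when active, were higher in 33 of 48 cases, with a median of 0.22 (adjusted p = 0.000116, and adjusted p = 0.753 with an estimated correlation). gadd45ba (0.74), dusp1 (0.79) and csrnp1b (0.48) were examples, of which dusp1 was 0.47 without normoxia 1, while socs3b had a log2 difference of -0.64. The list score was 0.44 in hypoxia 2 and between -0.33 and 0.17 in the other 5 arrays, and without hypoxia 2 or normoxia 2 the adjusted p of immediate early genes was 0.133 and 0.144, with a mean change minus that of other genes of 0.08 and 0.16 against 0.26. The glucocorticoid and stress axis had 17 of 29 genes higher and a median of 0.09 (adjusted p = 0.00644, and adjusted p = 0.753 with an estimated correlation). In this glucocorticoid and stress axis, klf9 was 8.28 in normoxia 1 and 10.37 to 11.89 in the others. Without normoxia 1 the mean change of the list minus that of other genes went from 0.275 to 0.124 (adjusted p = 0.0494), and with array spread as a covariate the adjusted p was 0.405. Glutamate receptors and transporters (24 of 36 higher, adjusted p = 0.0174) and voltage-gated ion channels (25 of 42 higher, adjusted p = 0.0229) had medians of 0.10 and 0.03. For these 2 lists adjusted p = 0.753 and 0.767 with an estimated correlation. No member of these 4 lists passed over all genes or over the list alone. The call of glutamate receptors and transporters was lost without hypoxia 3 (0.142) or normoxia 2 (0.476), and that of voltage-gated ion channels without hypoxia 3 (0.172), normoxia 2 (0.702) or normoxia 3 (0.0815). Both were lost without hypoxia 3 and normoxia 3 together (0.114 and 0.326). After quantile normalization of gene values both passed (camera adjusted p = 4.72e-06 and 6.85e-05), with medians of 0.29 and 0.19. With array spread as a covariate, added after the data were seen, both passed as well (1.86e-06 and 1.23e-08). The exact permutation p of their scores was 0.9 and 0.8.

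**Figure D2:**
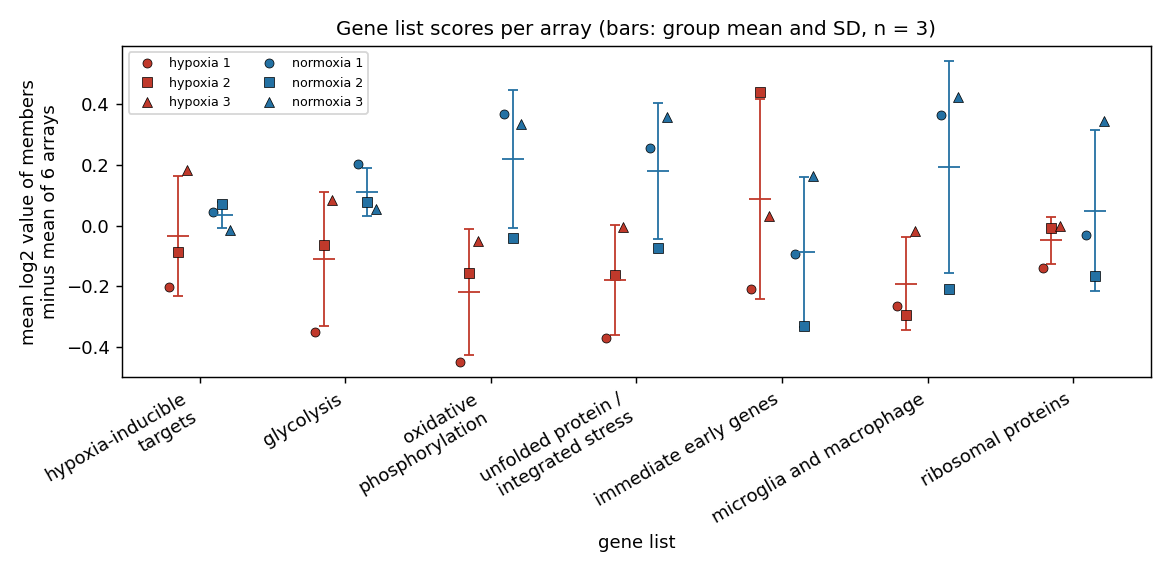
Scores of 7 gene lists in each array, as the mean log2 value of the members minus their mean over the 6 arrays (vertical axis), with group means and SDs as bars (n = 3). Scores of oxidative phosphorylation do not overlap between hypoxia (red) and normoxia (blue), and those of the other 6 lists shown do. Some lists not shown, such as endothelium, do not overlap either.

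In all, 22 of the 43 fixed lists passed camera with the preset correlation of 0.01, 10 up and 12 down. None passed with an estimated correlation, where none had an unadjusted p under 0.05 either, or by fry, where 4 did. Of the 22, oxidative phosphorylation, oxidative stress and Nrf2 targets, and angiogenesis and vascular signalling had an exact permutation p of 0.1. It was 0.2 for the TCA cycle, heat shock, the unfolded protein response, the proteasome and microglia, and 0.3 or more for the others. Examples were glycolysis (0.3), the glucocorticoid and stress axis (0.4), lens (0.5) and immediate early genes (0.6). Medians of the 14 pathway lists that did not pass lay between -0.23 for iron and haem metabolism and 0.02 for inflammation and cytokines. These include the Alzheimer's disease-associated genes, with 26 of 32 lower and adjusted p = 0.291, or 0.0127 without normoxia 2, and 0.0152 in the other direction with array spread as a covariate. Their median was at percentile 49.05 among random lists of like level, so the count is near the background. The members with the smallest p were inpp5d (-0.74), adam10a (-0.48), cd2ap (-0.41) and cdk5 (-0.43), of which adam10a was -0.29 without hypoxia 1, cdk5 -0.21 without normoxia 1 and cd2ap -0.66 without normoxia 2. None of these passed, and neither did appa (-0.07), appb (-0.04), bace1 (-0.20), psen2 (-0.15) or sorl1 (0.03), which ran from -0.42 for bace1 to 0.15 for sorl1 with 1 array left out. The circadian clock list (median -0.11) and the ribosomal proteins (-0.09) did not pass. Their signs depended on scaling, with medians of 0.03 and 0.05 with equal array medians and 0.03 and 0.07 after quantile normalization of gene values. Medians of the Alzheimer's disease-associated genes, GABA and glycine signalling, neuropeptides and p53 targets also changed sign between scalings.

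Markers of 3 brain cell types had lower group means in hypoxia, but normoxia 2 scored within or below the hypoxia arrays. Its scores were -0.211 for microglia and macrophage, -0.16 for radial glia and astroglia and -0.213 for oligodendrocyte and myelin. Scores in hypoxia ran from -0.296 to -0.0166, from -0.358 to -0.0548 and from -0.17 to -0.0941. The exact permutation p of these scores was 0.2, 0.3 and 0.4. Microglia and macrophage markers were lower in 25 of 31 cases, with a median of -0.41 (adjusted p = 0.0118, and adjusted p = 0.753 with an estimated correlation), and mpeg1.1 was 10.18 and 10.49 in normoxia 1 and normoxia 3 and 8.52 in normoxia 2. Radial glia and astroglia markers had 20 of 25 lower (median -0.34, adjusted p = 0.0212, and adjusted p = 0.753 with an estimated correlation), including the gap junction gene gja1b (-1.14) and s100b (-0.73), of which gja1b was -0.67 without hypoxia 1 and s100b -0.36 without normoxia 3. Oligodendrocyte and myelin markers had 18 of 21 lower (median -0.26, adjusted p = 0.0455, and adjusted p = 0.753 with an estimated correlation), with olig2 at -0.94 and the myelin gene mbpa at 0.03 (-0.16 to 0.17 with 1 array left out). No marker passed over all genes or over the list alone. As the mean change of members minus that of other genes, leaving out 1 array gave -0.48 to -0.18 for microglia and macrophage, -0.37 to -0.10 for radial glia and astroglia and -0.33 to -0.10 for oligodendrocyte and myelin. Without normoxia 3 the adjusted p of microglia and macrophage was 0.139 and that of radial glia and astroglia 0.366, which was 0.0824 without hypoxia 1. For oligodendrocyte and myelin it was 0.0549 without hypoxia 2, 0.175 without hypoxia 3, 0.156 without normoxia 1 and 0.364 without normoxia 3. Without hypoxia 3 and normoxia 3 together none of the 3 lists passed (0.0644, 0.271 and 0.484). With array spread as a covariate none of the 3 lists passed (0.575, 0.524 and 0.994), and after quantile normalization of gene values radial glia (0.0935) and oligodendrocytes (0.259) did not. That normalization gave medians of -0.24 for microglia, -0.12 for radial glia and -0.07 for oligodendrocytes. Equal array medians gave -0.27, -0.20 and -0.12. The oligodendrocyte median was at percentile 3.96 among random lists of like level, inside the middle 95%. Neuron markers did not pass (median -0.06), but did as lower without normoxia 2 (0.0362) and as higher with the spread covariate (3.11e-05).

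Lists of other tissues and of the pineal were higher. Lens (31 of 38 higher, adjusted p = 4.44e-06), retinal photoreceptor (32 of 44, adjusted p = 0.000161), skeletal muscle (35 of 44, adjusted p = 0.00106), epidermis and mucosa (27 of 43, adjusted p = 0.00998), cartilage and bone (19 of 26, adjusted p = 0.0124) and pineal markers (8 of 13, adjusted p = 0.0491) had medians from 0.09 to 0.23. All had adjusted p = 0.753 with an estimated correlation. With array spread as a covariate, added after the data were seen, lens, skeletal muscle, epidermis and mucosa, and cartilage and bone turned lower relative to other genes, lens (0.0456) and skeletal muscle (0.0405) past the threshold, and the other 4 lists did not pass. After quantile normalization of gene values none of the 6 passed, with adjusted p from 0.0583 for photoreceptor and 0.0808 for lens to 0.424 for cartilage. Medians of epidermis and cartilage lay inside the middle 95% of random lists of like level. Of the photoreceptor markers 16 of 44, and of the pineal markers 5 of 13, were highest in hypoxia 1, hypoxia 3 and normoxia 3, the arrays with high exorh, and 4 genes are in both lists. These arrays were picked because exorh, itself among the 5 pineal markers, was seen high there, so the counts decide nothing. Lens passed with each array left out, with a mean change minus that of other genes of 0.307 that was 0.115 without normoxia 1 and 0.541 without normoxia 2, and that of the other 5 lists also moved by more than 1.5 times. The calls of retinal photoreceptor (0.0945), skeletal muscle (0.164), epidermis and mucosa (0.452), cartilage and bone (0.147) and pineal (0.399) were lost without normoxia 1. Those of skeletal muscle (0.24) and cartilage and bone (0.0665) were lost without normoxia 3, and those of cartilage and bone (0.235) and pineal (0.321) without hypoxia 1. Without hypoxia 3 the calls of epidermis and mucosa (0.065) and pineal (0.238) were lost, as was that of pineal without normoxia 2 (0.359). Without hypoxia 3 and normoxia 3 together those of skeletal muscle (0.14) and epidermis and mucosa (0.0681) were lost. Their mean log2 levels were between 6.03 for lens and 7.21 for pineal, against 8.99 for oxidative phosphorylation. Over all genes, the 2596 with a mean above 9 had a median log2 difference of -0.19 and the 2001 with a mean below 6 one of 0.09.

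**Figure D3:**
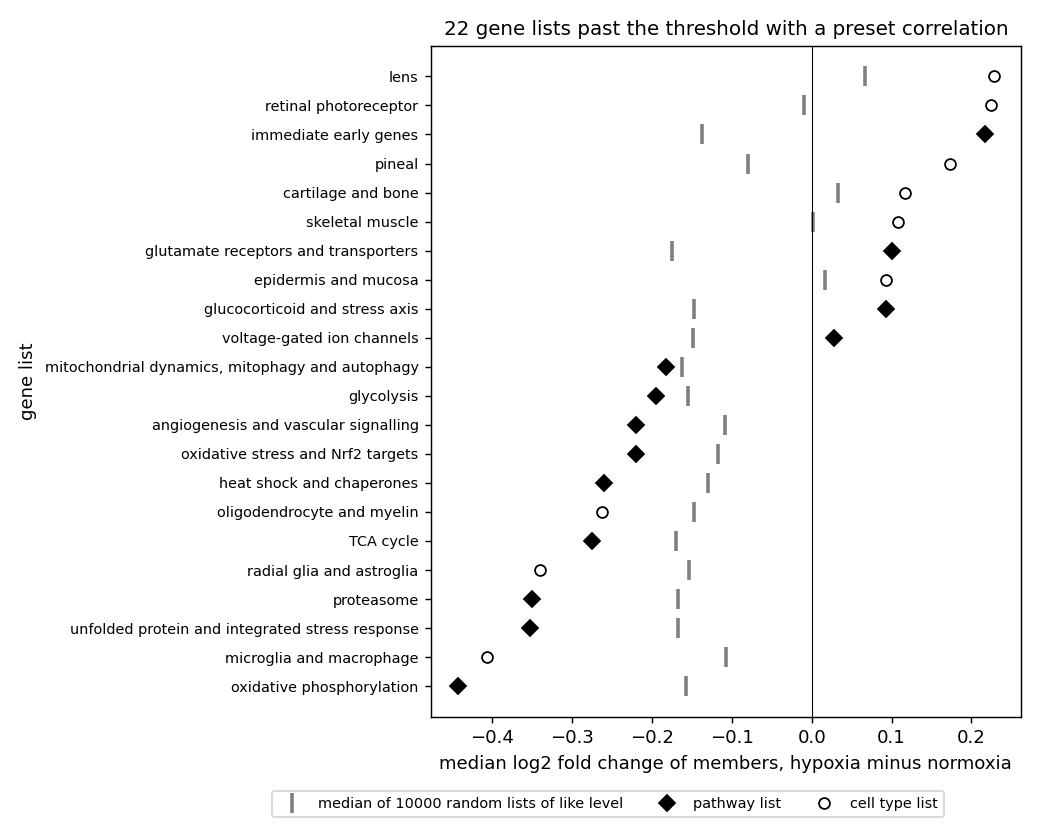
Median log2 fold change, hypoxia minus normoxia (horizontal axis), of the 22 gene lists past the threshold with a preset correlation, for pathway lists (diamonds) and cell type lists (circles). Grey bars are medians of 10000 random lists of like level, and oxidative phosphorylation at -0.44 lies farthest below 0.

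The arrays did not group by treatment. The first principal component held 54.6% of the variance, with scores of -35.6, -19.7 and 3.45 for hypoxia 1 to 3 and 56.8, -30.5 and 25.5 for normoxia 1 to 3, so that normoxia 2 lay between hypoxia 1 and hypoxia 2. The median gene value was 7.34 ± 0.03 in hypoxia and 7.48 ± 0.10 in normoxia (n = 3), with no overlap and an exact permutation p of 0.1, the smallest possible. The interquartile range of gene values was 1.68 ± 0.18 in hypoxia and 1.93 ± 0.38 in normoxia (n = 3, exact permutation p = 0.5), and was widest in normoxia 1 at 2.28. Array spread was also taken as the median of genes with a mean above 9 minus that of genes below 6. It ranked the arrays in the same order as the first component, from 3.71 in hypoxia 1 and 3.72 in normoxia 2 to 4.79 in normoxia 1. Correlations across genes were 0.956 to 0.965 within hypoxia, 0.918 to 0.961 within normoxia and 0.917 to 0.964 between the groups.

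**Figure D4:**
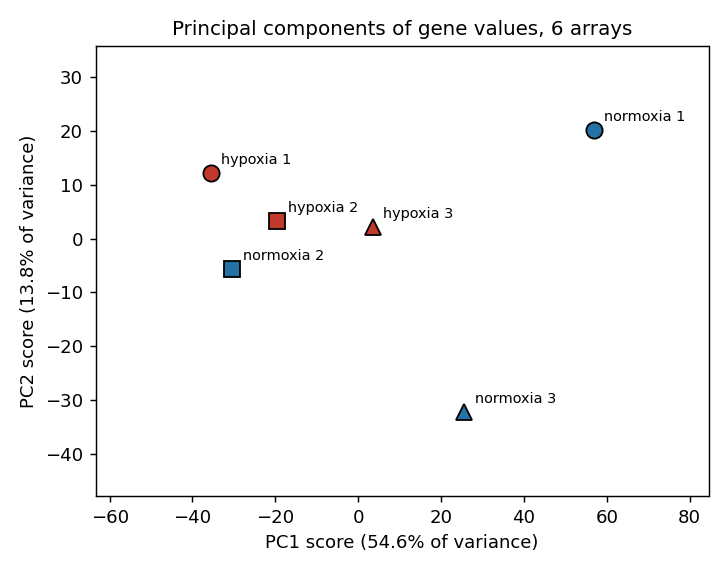
Scores of the 6 arrays on the first component (horizontal axis, 54.6% of variance) and the second (vertical axis, 13.8%), hypoxia in red and normoxia in blue. Normoxia 2 lies beside hypoxia 1 and hypoxia 2, and normoxia 1 is farthest to the right at 56.8.

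Hormone transcripts of the pituitary, a gland attached to the brain, differed between fish of the same group. Growth hormone, gh1, was 13.19 in hypoxia 3 and 12.83 in normoxia 3 and between 6.00 and 9.39 in the other arrays. prl (11.42 and 11.77) and pomca (10.23 and 10.24) were high in the same arrays and at most 7.20 and 6.74 in the others. The pineal opsin gene exorh was 10.75, 10.51 and 10.36 in hypoxia 1, hypoxia 3 and normoxia 3 and at most 7.49 in the others. The pituitary list did not differ between the groups (score difference -0.05, exact permutation p = 0.9). Without hypoxia 3 and normoxia 3 together, an alternative added after the data were seen, no gene passed, with 93 higher and 492 lower at an unadjusted p under 0.05. Of the 22 lists 15 stayed past the threshold and 7 did not, and 3 others passed: HIF pathway core (0.0251), ribosomal proteins (0.0253) and inflammation and cytokines (0.0326).

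**Figure D5:**
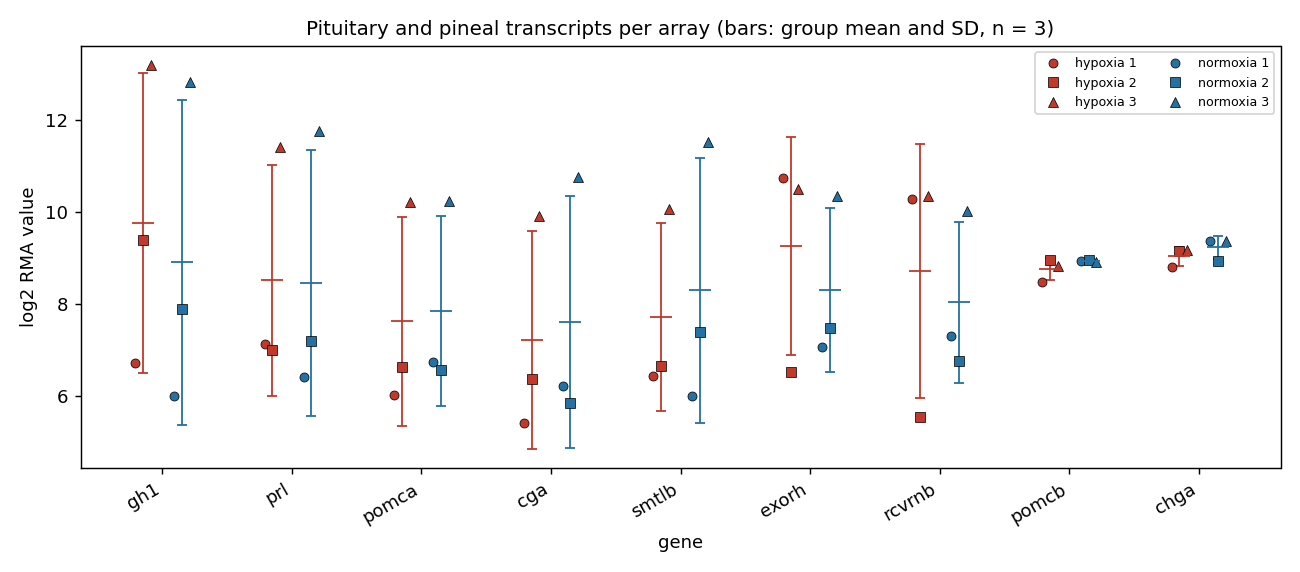
Log2 RMA values (vertical axis) of pituitary and pineal transcripts in each array, with group means and SDs as bars (n = 3). gh1, prl, pomca, cga and smtlb are highest in hypoxia 3 and normoxia 3, while pomcb and chga, which the brain also expresses, lie within a narrow range.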

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

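The replicate block, the scalings, the filters and the set tests were planned, while array spread as a covariate, quantile normalization of all rows and leaving out hypoxia 3 and normoxia 3 were chosen after the data were seen. No pairing by replicate number was seen over all genes: deviations of same-numbered arrays correlated at -0.336, 0.10 and 0.196, and hypoxia 1 correlated best with normoxia 2 (0.417). These values cannot exclude that same-numbered fish were handled together. The pituitary transcripts were high in the same-numbered hypoxia 3 and normoxia 3. With the replicate block 1 gene and 22 lists passed and no call of a gene or list changed. Leaving out 1 array gave 0 to 17 genes and 16 to 21 lists. The 17 came without normoxia 2. The cause was not tested unless stated. Against the 1 gene of the comparison, limma called 2 after quantile normalization of gene values, 3 after that of all rows, 3 at an adjusted p under 0.1, 0 with an intensity trend (smallest adjusted p 0.0582), 0 over every row of the table, and 0 without hypoxia 3 and normoxia 3. Filters at the 25th percentile and at the median level gave 0 and 0, since they remove LOC100535170. Array weights gave 7550 genes, with a weight of 39.9 on normoxia 3 and at most 1.76 on the others.

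Against 22 lists, 8 passed after quantile normalization of gene values, 13 and 11 with filters at the 25th percentile and the median, 11 with array spread as a covariate, 0 with an estimated correlation and 0 by fry. Of those 11, 4 were among the 22 in the same direction, 2 in the opposite one (lens and skeletal muscle), and 5 were not among the 22. Of the 22, 6 changed direction. Oxidative phosphorylation kept its call in 18 of 20 alternatives, with a median from -0.201 to -0.592, and lost it with an estimated correlation and by fry. As the mean log2 change of members minus that of other genes, lists past the threshold in either setting that reversed with the spread covariate were heat shock and chaperones (0.0275), Alzheimer's disease-associated genes (0.146), GABA and glycine signalling (0.228), mitochondrial dynamics, mitophagy and autophagy (0.0465), neuron (0.28), lens (-0.136), skeletal muscle (-0.143), epidermis and mucosa (-0.054) and cartilage and bone (-0.0399). Circadian clock, p53 targets, cell cycle, inflammation and T cell lists, which passed in neither, changed direction too. With array weights pineal (-0.393) and mbpa (-0.31 as log2 change) reversed. Leaving out 1 array gave -0.123 to 0.107 for GABA and glycine signalling and -0.0963 to 0.137 for ribosomal proteins, which was 0.132 without hypoxia 3 and normoxia 3. Equal array medians moved the share of genes higher in hypoxia from 38.9% to 59.1%.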

Other observations

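Tests of explanations in this part were chosen after the results they concern were seen, apart from the fixed gene lists they use. The full comparison and leaving out each array in turn were planned. A few clock and glucocorticoid-responsive genes, picked after their values were seen, differed between the normoxia fish. The clock repressor gene nr1d1 was 10.27 and 10.26 in normoxia 1 and normoxia 3, 8.55 in normoxia 2 and between 7.87 and 8.86 in hypoxia, and ciarta was 9.86 and 9.68 against 8.29 and 7.93 to 8.35. The glucocorticoid-induced gene fkbp5 was 7.27 in normoxia 1 and between 10.29 and 11.22 in the other 5 arrays, and klf9 was 8.28 in normoxia 1 and 10.37 to 11.89 elsewhere. Without normoxia 2, ptgr1.1 (-2.55), msrb2 (-2.06), slc7a11 (-1.68) and ciarta (-1.56) were among the 17 genes past the limma threshold, given as log2 differences. LOC100002043 had a log2 difference of -1.85 with adjusted p = 0.0565 in the full comparison.

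The real grouping of the arrays called 1 gene and 22 lists. Among the other splits the highest counts were 5 genes, in a split with 17 lists, and 23 lists, in a split with 0 genes. Among the 10 splits, 3 called at least 1 gene and 2 at least 22 lists, the real one included, and 10 splits are too few for a share under 0.05. The split of hypoxia 1, hypoxia 2 and normoxia 2 from the other arrays had 5520 genes at an unadjusted p under 0.05 against 1283 for the real split, which points to a structure of the samples other than the treatment. This split also follows array spread, as the median of genes with a mean above 9 minus that of genes below 6. It was 3.71, 3.98 and 3.72 in those arrays and 4.22, 4.79 and 4.36 in hypoxia 3, normoxia 1 and normoxia 3. Whether the spread comes from the arrays or from the fish was not tested.

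Oxidative phosphorylation genes were lower in the hypoxia arrays. Whether a shift that depends on level, from arrays of unequal spread, is the whole cause could not be settled. Relative to genes of like level the score was still lower by a difference of -0.278 (SE 0.0627, 95% interval -0.452 to -0.104, exact permutation p = 0.1, the smallest possible). With array spread as a covariate the list's median went from -0.443 to -0.201 (camera adjusted p = 0.00306 at the preset correlation). That preset correlation also let the list pass in 7 of the 9 other splits, so its p is weak evidence. The list was taken up because its camera p was the smallest of the 43 in these same arrays, and the interval does not allow for that choice. Poorer recovery of short abundant transcripts could not be told apart: ribosomal protein scores minus those of oxidative phosphorylation differed by 0.341 (SE 0.143, 95% interval -0.056 to 0.738), a difference that a first criterion of 2 SE would have counted against it before the wider interval, which fits 3 fish per group better, replaced it. The low-oxygen treatment itself stays open and untested beyond the group comparison.

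Pituitary transcripts were high in 2 arrays, 1 of each group. Of 20 measured pituitary markers in the fixed list, 10 were highest in hypoxia 3 and normoxia 3, and 6 of them by more than 1 log2 unit. These arrays were picked because members of the list were seen high there, so the count of 10 decides nothing, and whether pituitary tissue stayed with some brains at dissection stays open. In hypoxia 3 and normoxia 3 the log2 levels were 13.19 and 12.83 for gh1, 11.42 and 11.77 for prl and 10.23 and 10.24 for pomca, which do not rank these genes by abundance. The treatment does not account for the high values of normoxia 3, which was not exposed. The pituitary scores of the groups differed by -0.0543 with SDs of 0.81 and 0.94. With 1 high array in each group, a difference within these SDs was fixed when the pattern was seen. It therefore cannot exclude an effect of the treatment on these transcripts.

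Several of the genes with the smallest p belong to multi-copy families (trace amine, odorant and immune-type receptors, egg coat genes). For 519 genes matched by 25 name patterns, the median SD within groups was 0.406, at percentile 100 among random lists of like level, whose median was 0.299. A larger SD within groups does not by itself make p smaller. It therefore cannot show whether gene copies or alleles that differ between fish put family members among the smallest p. Whether their low level alone accounts for their number stays open: 12 were among the 100 genes with the smallest p, against a median of 4 in random lists of like level, but some families were picked because top genes belonged to them, which raises that count. Over the 260 genes of families not seen among the top genes it was 1, against a median of 1, which that selection lowers, so neither count decides.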
